A study of Mus musculus with 4 samples.

How the data were processed

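RNA was measured in the hippocampus of C57BL/6 mice aged 6 months, with 1 library for each of 4 genotypes: wild type (WT), Ogg1 knockout (Ogg1 KO), Mutyh knockout (Mutyh KO) and the knockout of both genes (DKO). Ogg1 encodes the DNA glycosylase that removes 8-oxoguanine paired with cytosine, and Mutyh encodes the glycosylase that removes adenine paired with 8-oxoguanine. Per the labels' protocols, total RNA was isolated with RNeasy columns, checked on a Bioanalyzer and made into libraries with standard Illumina reagents, and the series' design text names the HiSeq instrument. How many animals gave each RNA sample and their sex were not stated. The aligner, the counting program, the gene annotation and whether the libraries kept strand were not given in the sources used here. Per the submitters' processing notes, the mouse build was mm9.

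Each deposited table lists genes by symbol and gene ID and gives 4 values. The authors gave a count of unique reads per gene, per the file headers. The gene length in bases was deposited beside it by the authors and differed between libraries for 14 genes, of which 1 was compared (Gm14391). The authors gave coverage as the percent of the gene's length that reads covered, a meaning read from the name of that column in the file headers. The authors' RPKM values, also named in the file headers, equalled reads divided by length and by the library total given in the same header, to within rounding. Library totals equalled the sum of the listed reads, so genes without reads were not listed and were taken as 0 here. Rows with no gene symbol held 0.0179% to 0.0195% of the reads and were kept under their gene IDs.

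Everything else was computed from these tables. Of 18492 genes listed in any library, 16550 were listed in all 4, and 13186 had a mean over the libraries of at least 1 RPKM and were compared. The size of a difference was the log2 ratio of RPKM after adding a pseudocount of 1 RPKM, which understates differences of weakly expressed genes. Genes at least 2-fold different on that scale were counted for each knockout against WT and for the DKO against each single knockout. A fold given for a named gene is the ratio of reads per library total, with an exact conditional 95% interval. Such intervals, and the floor of 3 reads used in place of a count of 0, cover counting error only. With 1 library per genotype no difference has a replicate check, no p-value was computed across genes, and each comparison sets libraries side by side, not genotypes. The filter, pseudocount, counting rules, gene lists and the rule for naming genes were fixed before the data were examined.

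A departure from the sum of the single knockouts was the DKO log2 ratio to WT minus the log2 ratios of both single knockouts to WT. The effect of losing 1 gene was also compared across backgrounds by Pearson's r and Spearman's rho over genes, between library pairs that share no library. Genes are not independent replicates, so a bootstrap over genes gave the range of r as a description. Because the 3 comparisons with WT share 1 WT library, 4 unchanged libraries, WT included, were simulated 20 times and compared in the same way. Each was drawn from the mean share of reads over the deposited libraries, with counting error alone or with a coefficient of variation of 10% added. The simulated WT therefore carries none of the deviations of the deposited WT library. The calculation was tested on data simulated with counting error alone for Ogg1 KO against WT in 13172 genes: it found 14.7% of the genes set to differ 2-fold, 90.9% at 3-fold and 89.4% at 4-fold, and called 10 of 12979 unchanged genes. With a coefficient of variation of 10% added it found 20.6%, 90.9% and 84.85%, and called 7 of 12973. The 10% was assumed and the simulated genes varied independently, so these numbers do not estimate how many of the observed differences are false.

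Gene lists were written for DNA repair (base excision repair, p53 response), redox and energy metabolism (Nrf2, respiratory chain, ribosomal proteins, mitochondrially encoded transcripts), activity and hormones (immediate early, estrogen, circadian clock, glucocorticoid), neurotransmission (monoamine, GABA, glutamate, synaptic plasticity), hippocampal neurons (dentate gyrus, CA1, CA2 and CA3, neurogenesis), other cells (astrocyte, oligodendrocyte, microglia, endothelial, blood, choroid plexus, ependymal, meningeal), nearby regions (thalamus, striatum, neocortex, hypothalamus), immunity and stress (interferon, MHC, inflammation, heat shock) and sample identity (Y-linked and X-inactivation, strain-variable genes). A list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Random lists hold unrelated genes, so a percentile does not measure the spread between animals. None of the mitochondrially encoded transcripts was listed under its name, so 35 of the 36 lists were compared. Lists for liver, heart muscle, intestine, pituitary and lateral hypothalamus were written after the data had been seen.

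Named genes were Ogg1 and Mutyh, the 10 highest and 10 lowest log2 ratios in each comparison with WT, list members past 0.58 in size (up to 2 each way), the 5 largest departures each way, the 5 genes with the largest same-signed ratios on both backgrounds each way, and up to 4 members of each list outside the 1st to 99th percentiles. Not every gene of a part is printed: those printed are its first by rank, grouped by topic and so not always in that order. Predicted, clone-named, microRNA and small nucleolar RNA genes were left out of the rule. A few further genes, called out in the text, were chosen after their values were seen.

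Chromosomal neighbours within 10 Mb of Ogg1 and Mutyh, and gene names, came from a RefSeq table of assembly GRCm38.p6, which held 99.5% of the gene IDs. That build is not the one the tables were made on, so no coordinate is given. Alternatives were other pseudocounts (0.1 and 5 RPKM), no filter and a filter at 5 RPKM, scaling by the median ratio or by trimmed means (30% trim), a 1.5-fold limit, intervals excluding 1, other neighbour distances (5 and 20 Mb), and leaving out sets of genes. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.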

Results

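Hippocampal transcripts were measured in 4 libraries, 1 each from WT, Ogg1 KO, Mutyh KO and DKO mice. The libraries held 18.12 M (WT), 17.02 M (Ogg1 KO), 17.15 M (Mutyh KO) and 18.20 M (DKO) unique reads in genes (M, mega), and listed 17419, 17398, 17556 and 17587 genes with at least 1 read. Ribosomal RNA genes took 0.733% of the reads in WT, 0.351% in Ogg1 KO, 1.37% in Mutyh KO and 1.48% in DKO. The design sets both single losses and their combination against WT, and so asks which transcripts differ without each glycosylase and without both.

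Ogg1 (gene ID 18294) had 94 reads in WT, 130 in Ogg1 KO, 81 in Mutyh KO and 103 in DKO, or 3.33, 4.91, 3.04 and 3.64 RPKM. Its read total in the library labelled Ogg1 KO was 1.47-fold the WT value (1.12 to 1.94), and in DKO 1.09-fold (0.817 to 1.46), so the total alone runs against both labels, on which every direction given for Ogg1 KO and DKO rests. The covered share of Ogg1 separated the same libraries, at 86.7% in WT and 81.5% in Mutyh KO against 47.2% in Ogg1 KO and 46.4% in DKO. Genes of like length and read number had a median coverage of 88.0% in the Ogg1 KO library and 84.1% in DKO, which placed Ogg1 at percentiles 2.75 and 3.80. Which part of Ogg1 was deleted was not given in the sources used here, and reads of a gene overlapping it on the other strand cannot be told apart without strand. Mutyh (gene ID 70603) had 39 reads in WT, 35 in Ogg1 KO, 15 in Mutyh KO and 20 in DKO. Its fold to WT was 0.406 (0.208 to 0.754) in Mutyh KO and 0.510 (0.282 to 0.897) in DKO, with coverage of 18.4% and 27.7% against 55.9% in WT. Genes of like length and read number had a median coverage of 30.2% in Mutyh KO and 37.3% in DKO, which placed Mutyh at percentiles 7.74 and 15.2.

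**Figure D1:**
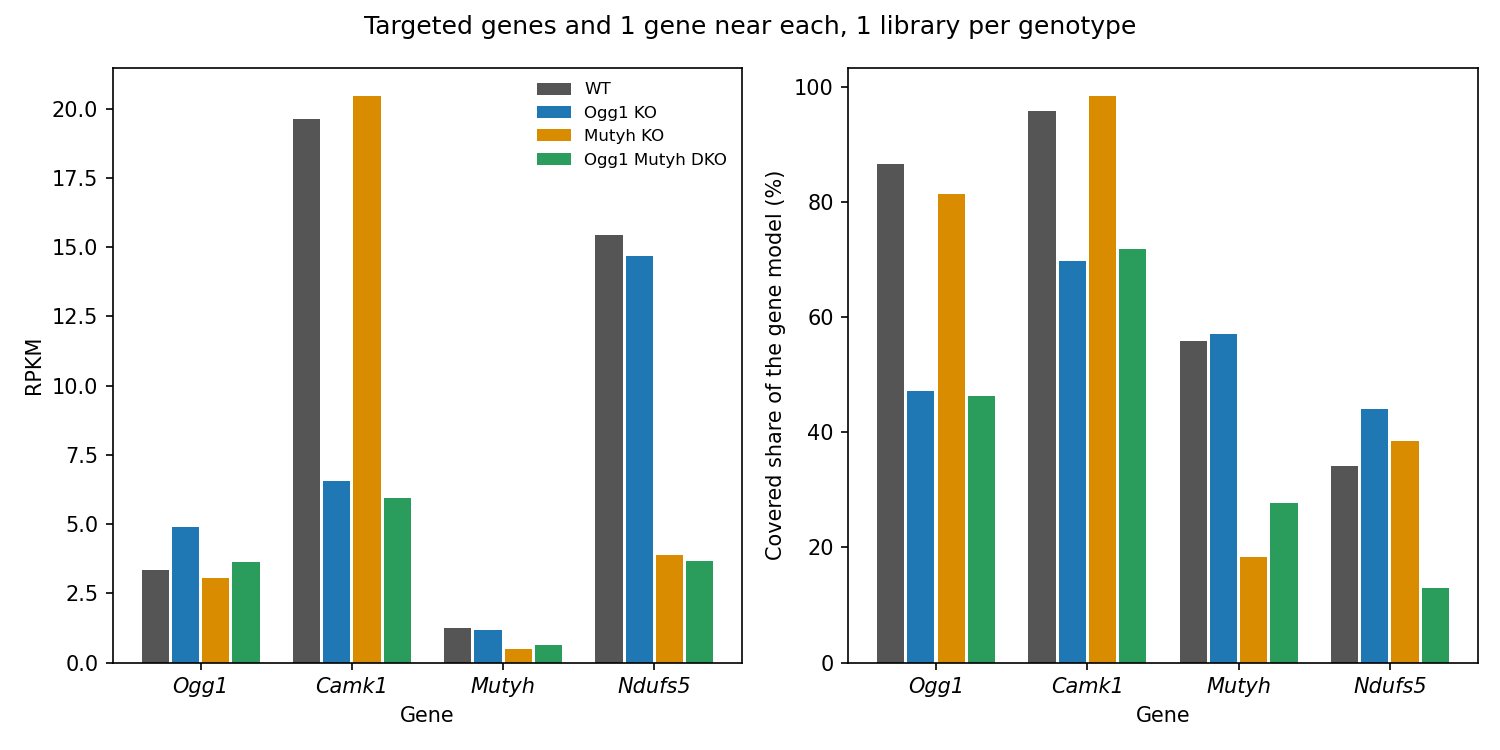
RPKM (left) and covered share of the gene in percent (right) of Ogg1, Mutyh and the nearby genes Camk1 and Ndufs5, 1 bar per library. Camk1 had 19.6 RPKM in WT and 20.5 in Mutyh KO, against 6.55 and 5.94 in the libraries labelled Ogg1 KO and DKO.

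In the library labelled Ogg1 KO, most of the genes furthest above WT were those of the choroid plexus, the epithelium that secretes cerebrospinal fluid, with the intestinal genes Apoa4 and Fabp2 among them. Ttr, the carrier of thyroid hormone, had 47882 reads against 3542 in WT, 14.4-fold higher (13.9 to 14.9). The potassium channel genes Kcnj13 and Kcne2 were 13.2-fold (9.71 to 18.3) and 12.4-fold (8.66 to 18.5) higher, and Tmem72 39.7-fold (23.4 to 73.1). Folr1, a folate receptor, was 11.9-fold higher, Cldn2, a tight junction protein, 13.3-fold, F5, coagulation factor V, 9.86-fold, and Enpp2, the enzyme that makes lysophosphatidic acid, 6.27-fold. At the other end, the plasma protein gene Alb had 752 reads in WT and 0 in Ogg1 KO, at least 191-fold lower by its interval. The heart actin gene Actc1 had 128 and 0, at least 32.1-fold lower.

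Further genes low in the Ogg1 KO library were Myl2, a heart myosin light chain (0.0453-fold, 0.00533 to 0.173), the liver genes Mup20, Serpina1e and Serpina3k (at least 10.2-fold, 14.1-fold and 14.6-fold lower by their intervals), and Lcn2, an iron-binding acute phase protein, with 3 reads against 57. Mup20 and the Serpina genes belong to families of near-identical copies among which the counting could split reads. The structural RNAs Rn7sk and Rn18s were at 0.228-fold and 0.296-fold, and the ribosomal RNA share, which includes Rn18s, was lowest in this library. Camk1, a calcium- and calmodulin-dependent kinase next to Ogg1, was at 0.334-fold (0.278 to 0.400). The intestinal genes Apoa4 (171 reads against 1, 182-fold, 32.2 to 7230) and Fabp2 (62 reads against 0, at least 17.4-fold by its interval) were higher. Of the 13186 genes, 73 were at least 2-fold higher and 28 at least 2-fold lower than in WT, 90 of the 101 had intervals excluding 1, and 97.8% of genes lay within 1.5-fold. Leaving out listed genes of other tissues and sex-linked genes, a choice made after seeing the data, left 61 genes.

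All 18 choroid plexus genes were higher in Ogg1 KO, with a median log2 ratio of 2.32, above every random list, and their share of reads was 0.514% against 0.0568% in WT. Blood cell transcripts moved the same way, with a median of 0.84 over 5 of 5 members higher. Beta-s, a beta-globin gene, was 2.09-fold higher and Hba-a2, an alpha-globin gene, 2.25-fold, and both share sequence with near copies. Meningeal genes had a median of 0.37 (12 of 14 higher, above every random list), led by the sulfate transporter Slc13a4 at 3.72-fold and the growth factor Igf2 at 3.22-fold. MHC genes also had a median of 0.37 (11 of 12 higher). The class II genes Cd74 (3.64-fold, 2.79 to 4.80) and H2-Aa (4.97-fold, 2.96 to 8.78) led them. Endothelial genes stood at 0.15 (percentile 99.3), with Rgs5 at 1.47-fold and Acta2 at 1.41-fold.

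Heat shock and unfolded protein response genes were lower in Ogg1 KO, 17 of 18 of them, with a median of -0.28, below every random list. Hspa1b, an inducible Hsp70 gene with a near-identical copy (Hspa1a), was at 0.479-fold (0.378 to 0.604), the endoplasmic reticulum gene Sdf2l1 at 0.570-fold and the chaperone Hspa5 at 0.666-fold. Dentate gyrus granule cell genes were lower in 12 of 14 cases (median -0.17, percentile 0.02), with C1ql2, a synaptic protein of mossy fibres, at 0.767-fold. Glucocorticoid-responsive genes had a median of -0.13 (percentile 0.12, 10 of 18 lower). Plin4 at 0.535-fold was among the lower members, and Crh at 1.82-fold was above WT. Outside these lists, Grin2b, a subunit of NMDA receptors, was at 0.534-fold and Grin2a at 1.94-fold, Gabrb1 at 0.650-fold and Pvalb at 1.64-fold. The serotonin receptor Htr2c, which the choroid plexus also expresses, was 1.68-fold higher, and Prlr, a choroid plexus and estrogen list member, 6.07-fold. Bok was at 0.565-fold, Coch at 2.22-fold, Stc2 at 0.422-fold, Perp at 2.0-fold and the myelin gene Opalin at 1.66-fold.

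**Figure D2:**
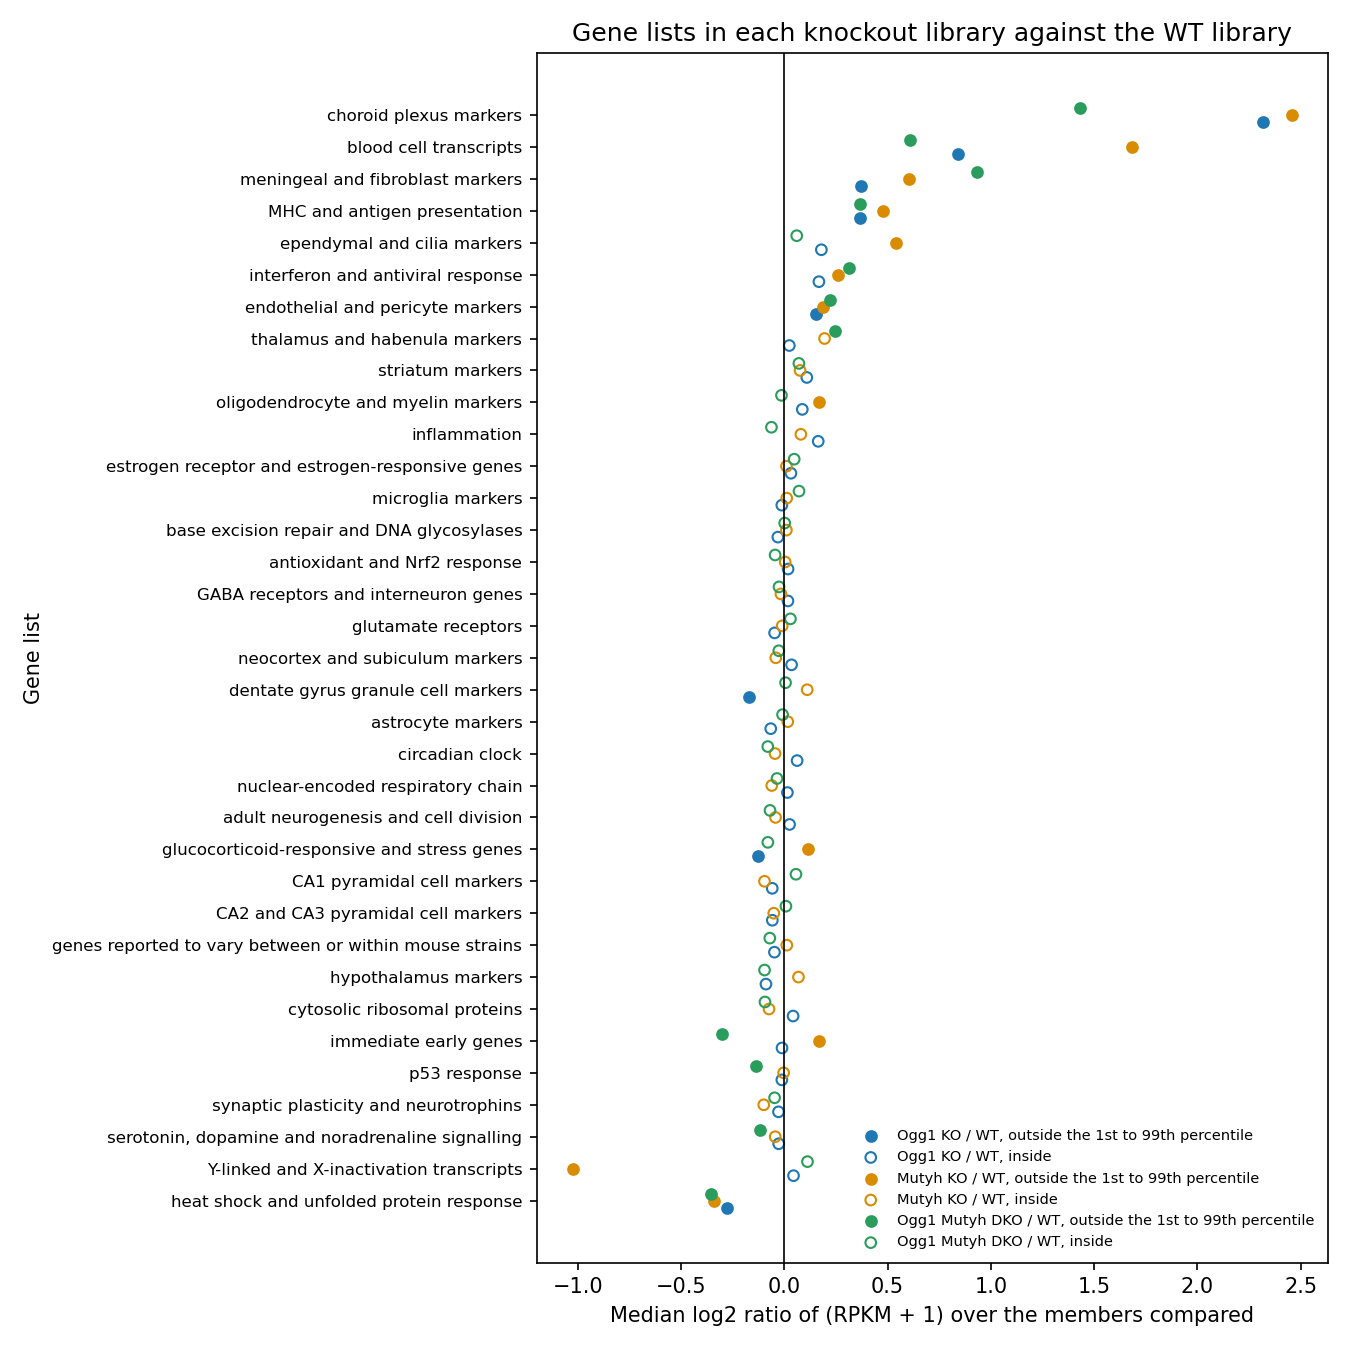
Median log2 ratio of each gene list in the comparisons with WT, with the lists outside the 1st to 99th percentiles of 10000 expression-matched random lists marked. Among these lists, all fixed before the data were seen, that of the choroid plexus lies furthest above 0, at 2.32 in Ogg1 KO, 2.46 in Mutyh KO and 1.43 in DKO.

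In the Mutyh KO library, Xist, the RNA that coats the inactive X chromosome, was furthest above WT, with 10307 reads against 14 (778-fold, 463 to 1424). The Y-linked genes Ddx3y (0.374-fold), Eif2s3y (0.426-fold), Uty (0.323-fold) and Kdm5d (0.403-fold) were lower but present, at 87 to 289 reads. Every comparison with the Mutyh KO library, DKO against it included, is therefore also one between libraries of different sex-linked content. Choroid plexus genes were also far above WT, with Ttr at 13.7-fold (13.3 to 14.2), Kcnj13 at 16.2-fold (11.9 to 22.4), Prlr at 13.9-fold, Folr1 at 14.3-fold, F5 at 13.4-fold, Enpp2 at 6.59-fold, Kcne2 at 11.7-fold, Slc4a5, a bicarbonate transporter, at 15.5-fold and Cldn2 at 14.0-fold. Ndufs5, a subunit of respiratory complex I, was lowest, with 36 reads against 151 (0.252-fold, 0.170 to 0.364), and its near-identical copy BC002163, which the naming rule leaves out for its clone name, had 124 reads against 1, a log2 ratio of 3.80 that only Xist exceeded.

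Other genes low in Mutyh KO were Hspa1b (0.379-fold, 0.292 to 0.486), Lcn2 (0.389-fold), Plac9a (0.519-fold) and Erdr1 (0.609-fold), while the small nuclear RNA gene Rnu1a1 rested on 1 read against 5 (0.211-fold, 0.00447 to 1.89). In all, 98 genes were at least 2-fold higher and 12 at least 2-fold lower than in WT. Of these 110 genes, 98 had intervals excluding 1, and 97.5% of all genes lay within 1.5-fold.

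The choroid plexus list had a median of 2.46 in Mutyh KO, all 18 members higher and 0.532% of reads, and the blood list a median of 1.68, with Beta-s at 3.49-fold, Hbb-b1 at 3.90-fold and Hba-a2 at 3.66-fold. Meningeal genes (0.60, 14 of 14 higher, Igf2 4.65-fold, Slc13a4 5.23-fold, Aldh1a2 2.36-fold) and ependymal and cilia genes (0.54, 12 of 12 higher, Tmem212 2.33-fold, Rsph1 2.05-fold) also lay above every random list. MHC genes had a median of 0.48, with H2-Aa at 4.29-fold (2.53 to 7.63), Cd74 at 2.58-fold and H2-Eb1 at 3.39-fold. Interferon genes stood at 0.26 (percentile 99.4, 15 of 16 higher), with the viral release inhibitor Bst2 at 1.81-fold. Endothelial genes stood at 0.19 (percentile 99.9, 16 of 18 higher), with Vwf, the clotting glycoprotein, at 1.40-fold. Oligodendrocyte and myelin genes had a median of 0.17, above every random list, with Opalin at 1.59-fold and Mog at 1.35-fold.

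Immediate early genes, which respond to neuronal activity, were higher in Mutyh KO for 17 of 24 members (median 0.17, above every random list), with Fos at 1.44-fold, Fosb at 1.46-fold and Sik1 at 1.38-fold. Glucocorticoid-responsive genes had a median of 0.11 (percentile 99.2, 12 of 18 higher), with the receptor gene Crhr1 at 0.704-fold and the kinase gene Sgk1 at 1.27-fold. Heat shock genes were lower for 18 of 18 members, with a median of -0.34, below every random list. The Y-linked and X-inactivation list had a median of -1.02, set by its Y-linked members. The neuropeptide genes Pmch (67 reads against 2, 35.4-fold, 9.43 to 298) and Hcrt (62 against 16, 4.10-fold), made in the lateral hypothalamus, were higher. Among further members past the size limit, Grin2a was 2.23-fold higher, Perp 2.33-fold, Coch 1.94-fold, Htr2c 1.79-fold and Entpd4 2.49-fold.

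In the library labelled DKO, BC002163 had the highest log2 ratio to WT (3.97, 149 reads against 1), followed by Gh, the growth hormone gene of the pituitary, with 256 reads against 4 (63.7-fold, 24.6 to 236). Choroid plexus genes were higher again, all by less than in Ogg1 KO and, except for Tmem72, by less than in Mutyh KO: Ttr 6.99-fold (6.75 to 7.25), Kcnj13 7.74-fold, Tmem72 18.3-fold (10.7 to 34.0), Folr1 7.04-fold, F5 5.79-fold and Enpp2 3.55-fold. H2-Aa was 6.30-fold higher (3.82 to 11.02), Slc13a4 3.87-fold (3.36 to 4.47) and the ribosomal RNA gene Rs5-8s1 4.24-fold. Ndufs5 (0.237-fold, 0.16 to 0.343) and Camk1 (0.303-fold, 0.251 to 0.363) were both low, as each was in 1 of the single knockouts.

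Further genes low in DKO were Lcn2 (0.122-fold, 7 reads against 57), Plac9a (0.332-fold), the adaptor gene Dok3 (0.464-fold), Hcrt (0.187-fold, 3 reads against 16), Hspa1b (0.411-fold), Fos (0.468-fold, 0.373 to 0.585), Pglyrp1, a peptidoglycan recognition protein (0.483-fold), and the imprinted gene Peg10 (0.520-fold). At least 2-fold differences numbered 72 higher and 6 lower, 72 of the 78 had intervals excluding 1, and 98% of genes lay within 1.5-fold.

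The choroid plexus list had a median of 1.43 in DKO, 18 of 18 members higher and 0.267% of reads. Meningeal genes had their highest median here, 0.93 with 14 of 14 higher, and included Aldh1a2 at 3.40-fold (2.74 to 4.24) and Igf2 at 2.43-fold. Blood transcripts stood at 0.61, with Hba-a2 at 1.82-fold and the erythroid enzyme gene Alas2 at 2.08-fold. Endothelial and pericyte genes had a median of 0.22, above every random list, with the smooth muscle genes Acta2, Myh11 and Tagln at 1.65-fold, 1.70-fold and 1.65-fold and Vwf at 1.76-fold. MHC genes were higher for 12 of 12 members (median 0.37, Cd74 3.79-fold, H2-Eb1 4.09-fold) and interferon genes for 16 of 16 (median 0.31, percentile 99.99), with the GTPase gene Gbp2 at 1.99-fold and Ifit1 at 1.68-fold. Thalamus and habenula genes stood at 0.24 (percentile 99.99, 11 of 16 higher), with Tnnt1 at 2.76-fold (36 reads against 13), Ramp3 at 1.70-fold, Slc17a6, a glutamate transporter of vesicles, at 1.5-fold and Zic1 at 0.717-fold.

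Immediate early genes were lower in DKO for 23 of 24 members, with a median of -0.30, below every random list. Arc, which acts at synapses, was at 0.58-fold (0.547 to 0.614), Npas4 at 0.605-fold and Egr2 at 0.431-fold. Heat shock genes were lower for 18 of 18 members (median -0.35, below every random list), with Sdf2l1 at 0.561-fold, Hspb1 at 0.578-fold and Creld2 at 0.631-fold. Between knockouts the heat shock medians were -0.05 (DKO against Ogg1 KO) and -0.04 (DKO against Mutyh KO), inside the percentiles 1 to 99, so it was the WT library that stood apart. The p53 list had a median of -0.14 (percentile 0.22, 11 of 16 lower), with Perp, in the other direction, at 2.28-fold, Sesn2 at 0.741-fold and Btg2 at 0.740-fold. Monoamine signalling genes had a median of -0.12 (percentile 0.02, 15 of 22 lower), with the dopamine receptor Drd2 at 0.597-fold and the adrenergic receptor Adra2a at 0.692-fold. Grin2a was at 3.21-fold (2.82 to 3.65), Ndufa1 at 0.640-fold and Wdfy1 at 0.559-fold.

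The remaining list medians, in the order Ogg1 KO, Mutyh KO and DKO against WT, stayed between percentiles 1 and 99. For DNA repair and metabolism they were -0.03, 0.01 and 0.00 for base excision repair genes (10 of 20 higher in each), -0.01 and -0.00 for the p53 list in the single knockouts, 0.02, 0.00 and -0.05 for Nrf2 genes, 0.01, -0.06 and -0.04 for the respiratory chain, and 0.04, -0.07 and -0.09 for ribosomal proteins. Transmission and hormone lists gave 0.02, -0.02 and -0.03 for GABA genes, -0.05, -0.01 and 0.03 for glutamate receptors, -0.03, -0.10 and -0.05 for synaptic plasticity, -0.03 and -0.04 for monoamine genes in the single knockouts, 0.03, 0.01 and 0.05 for estrogen genes, and 0.06, -0.05 and -0.08 for clock genes. Immediate early genes in Ogg1 KO stood at -0.01 and glucocorticoid genes in DKO at -0.08.

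Lists of hippocampal neurons and glia gave -0.06, -0.10 and 0.06 for CA1, -0.06, -0.05 and 0.01 for CA2 and CA3, 0.02, -0.04 and -0.07 for neurogenesis, -0.07, 0.02 and -0.01 for astrocytes and -0.01, 0.01 and 0.07 for microglia. Dentate genes stood at 0.11 in Mutyh KO and 0.01 in DKO, oligodendrocyte genes at 0.09 in Ogg1 KO and -0.01 in DKO, and ependymal genes at 0.18 in Ogg1 KO and 0.06 in DKO. Regional lists gave 0.11, 0.08 and 0.07 for striatum, 0.03, -0.04 and -0.03 for neocortex, -0.09, 0.07 and -0.10 for hypothalamus, and 0.02 and 0.19 for thalamus in the single knockouts. Inflammation genes stood at 0.16, 0.08 and -0.06, interferon genes in Ogg1 KO at 0.17, strain-variable genes at -0.05, 0.01 and -0.07, and the Y-linked and X-inactivation list at 0.04 in Ogg1 KO and 0.11 in DKO. Over the 5 comparisons, 58 of 175 list medians lay outside the 1st to 99th percentiles, and 31 of these were among the 105 comparisons with WT. If the genes of a list varied independently, 3.5 would be expected. Genes of a list can vary together between animals or dissections, so the excess does not measure an effect of genotype. In 18 cases a median of at most 0.0236 in size changed sign under another scaling, among them lists in this and the preceding paragraph.

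Transcripts of tissues outside the brain set the Ogg1 KO library apart from the other 3, in lists written after the data had been seen. The liver list held 20.6 reads per M reads in Ogg1 KO against 96.5 in WT, 96.1 in Mutyh KO and 101 in DKO, and the heart muscle list 16.7 against 48.7, 58.1 and 56.5. Median log2 ratios to WT of the 13 liver genes compared were -1.39 in Ogg1 KO, 0.02 in Mutyh KO and 0.06 in DKO, and with counts of 0 set to the floor of 3 reads the Ogg1 KO median of reads per total was -3.72. For the 10 heart genes they were -0.80 (-1.42 at the floor), 0.17 and 0.11. Intestinal genes went the other way, with 118 reads per M reads in Ogg1 KO against 82.8 in WT, and medians over 6 genes of 0.93 (1.28 at the floor), 0.27 and 0.09. Lct, which is also on the dentate gyrus list, held 1014 of the list's 2014 reads in Ogg1 KO and 1258 of 1501 in WT, and the other 20 genes held 58.7 against 13.4 reads per M reads. Reg3b had 47 reads in Ogg1 KO, Reg3g 37 and Guca2b 38, where the other libraries had at most 2. Of the pituitary list 1 gene, Gh, was compared (log2 ratio 3.70 in DKO), and the list held 20.6 reads per M reads in DKO against 0.938 in WT. The lateral hypothalamus pair, Pmch and Hcrt, had medians of -0.58, 1.98 and -0.53.

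**Figure D3:**
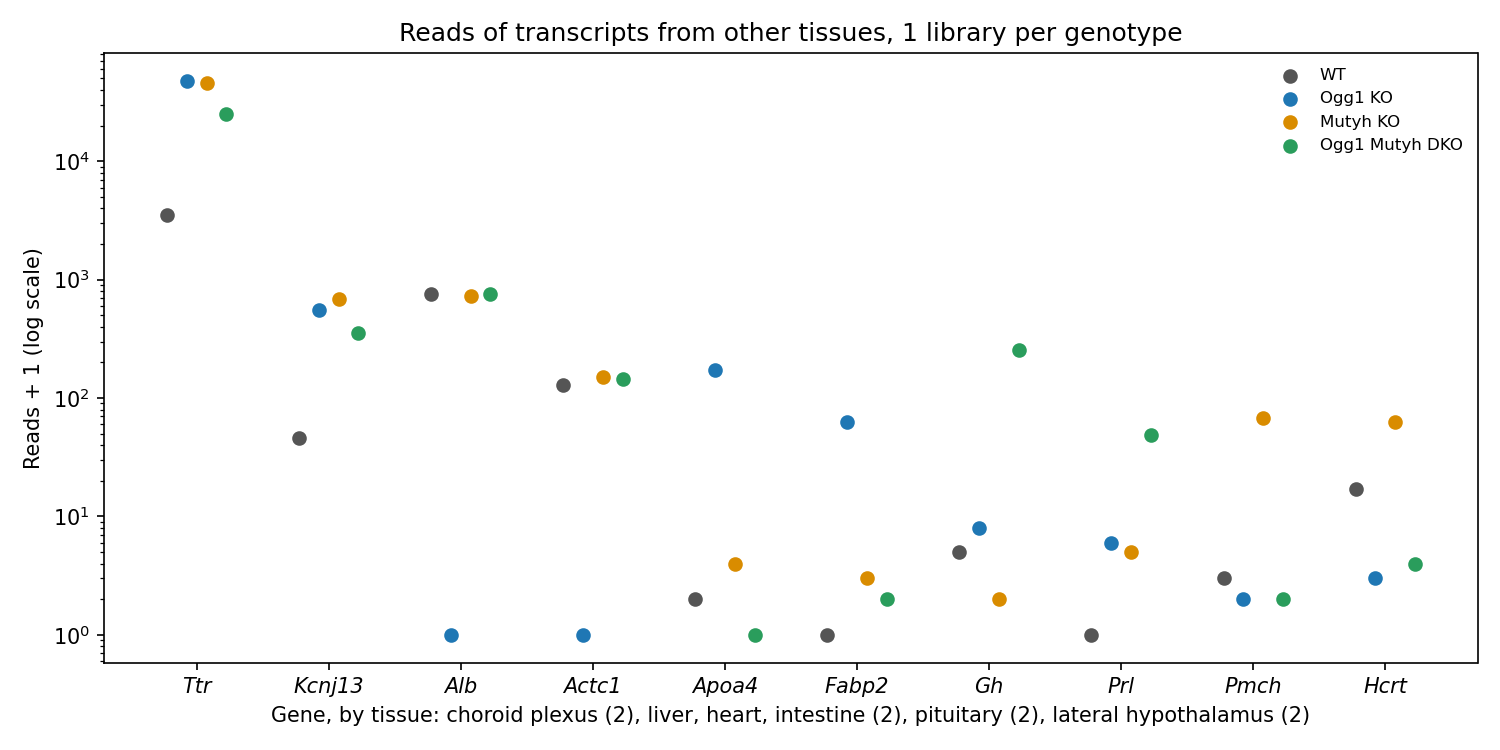
Reads, plus 1, on a log scale for genes of the choroid plexus, liver, heart, intestine, pituitary and lateral hypothalamus in the 4 libraries, 1 point per library. Alb had 752 reads in WT, 723 in Mutyh KO, 761 in DKO and 0 in Ogg1 KO, and Gh 256 in DKO against at most 7 in the others.

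Loss of Mutyh in the absence of Ogg1 was read from the library labelled DKO against that labelled Ogg1 KO, where immediate early genes were lower for 23 of 24 members (median -0.29, below every random list), with Fos at 0.454-fold (0.361 to 0.568), Arc at 0.600-fold, Egr4 at 0.724-fold and Nr4a1 at 0.742-fold. These immediate early genes also had negative medians in DKO against WT (-0.30) and against Mutyh KO (-0.47). It was thus the DKO library that stood apart for them, and the value does not single out loss of Mutyh. Choroid plexus genes were lower against Ogg1 KO (median -0.79, 18 of 18), with Kcne2 at 0.350-fold and Ttr at 0.486-fold. The liver and heart genes that lacked reads in Ogg1 KO were present in DKO, with Alb at 761 reads and Actc1 at 144. Dentate gyrus genes were higher for 12 of 14 members (0.16, percentile 99.98), with Tdo2 at 1.57-fold and Maml2 at 1.41-fold, and CA1 genes for 9 of 10 (0.14, percentile 99.9), with Gpr161 at 1.31-fold and Fibcd1 at 1.27-fold. Against WT the dentate median was -0.17 in Ogg1 KO and 0.01 in DKO, so for this list the Ogg1 KO library stood apart.

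Meningeal genes (0.37, Crabp2 2.24-fold), endothelial genes (0.15, Vwf 1.59-fold), thalamus genes (0.15, Tnnt1 1.87-fold but Tac2 0.675-fold), MHC genes (0.14, Psmb8 1.55-fold), microglial genes (0.10, 11 of 16 higher, Aif1 1.34-fold, 0.877 to 2.08) and astrocyte genes (0.07, 11 of 16 higher, S100b 1.40-fold) were also above the 99th percentile in DKO against Ogg1 KO. Below the 1st lay blood (-0.28, Beta-s 0.717-fold), neurogenesis (-0.21, Hes5 0.748-fold), striatum (-0.18, 10 of 12 lower), ependymal (-0.17, Dynlrb2 0.540-fold) and ribosomal protein genes (-0.15, Rps28 0.600-fold). At least 2-fold differences numbered 40 higher and 11 lower, with 98.4% of genes within 1.5-fold. Without the listed genes of other tissues and sex-linked genes 31 remained of these 51, and without small and ribosomal RNA genes also 31, both choices made after seeing the data. With no filter on the mean the count was 85.

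Loss of Ogg1 in the absence of Mutyh was read from the library labelled DKO against Mutyh KO. Xist was at 0.00265-fold, and the Y-linked genes Ddx3y (2.88-fold), Eif2s3y (2.64-fold) and Uty (3.43-fold) were higher, so that the sex-linked list had a median of 1.14. Choroid plexus genes were lower (median -0.99, 17 of 18 lower), with Prlr at 0.216-fold (0.20 to 0.233), Col8a1 at 0.313-fold and Kcne2 at 0.371-fold, and blood transcripts too (-1.03, 5 of 5 lower, Beta-s 0.430-fold). Immediate early genes were lower for 21 of 24 members (median -0.47), with Fos at 0.324-fold (0.261 to 0.401), Egr2 at 0.294-fold (0.187 to 0.450) and Npas4 at 0.522-fold. Their medians in DKO against WT and Ogg1 KO were negative as well (-0.30 and -0.29), so this value does not single out loss of Ogg1.

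Ependymal genes (-0.47, Rsph1 0.486-fold), inflammation genes (-0.22, Lcn2 0.314-fold), glucocorticoid genes (-0.14, Cdkn1a 0.658-fold), strain-variable genes (-0.11, 7 of 11 lower and 1 at least 2-fold higher, Entpd4 0.398-fold) and oligodendrocyte genes (-0.10, Mobp 0.820-fold) were also below the 1st percentile in DKO against Mutyh KO. Above the 99th lay meningeal genes (0.24, Crabp2 2.13-fold but Igf2 0.522-fold), CA1 genes (0.20, Gpr161 1.39-fold, Nov 1.29-fold) and MHC genes (0.17, Cd74 1.47-fold). At least 2-fold differences numbered 12 higher and 28 lower, with 98.7% of genes within 1.5-fold, and 20 of the 40 remained without the listed genes of other tissues and sex-linked genes, a choice made after seeing the data.

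Genes that differed in the same direction on both backgrounds were few among the 13186 compared. For loss of Ogg1 (against WT, then DKO against Mutyh KO), the higher genes were led by Mid1, a ubiquitin ligase gene at the pseudoautosomal boundary of mice (4.85-fold and 2.65-fold), followed by Spp1, the matrix protein osteopontin (1.53-fold both times). The lower ones were led by Camk1 (0.334-fold and 0.290-fold), Hcrt (2 reads against 16, then 3 against 62), Lcn2 and Agxt2l1 (0.612-fold and 0.597-fold). Pmch, also made in the lateral hypothalamus, had 67 reads in Mutyh KO against 2 in WT. For loss of Mutyh (against WT, then DKO against Ogg1 KO), the ribosomal RNA genes Rs5-8s1, Rn18s and Rn28s1 and the neuronal transcript Cdr1 (2.46-fold and 1.86-fold) were higher. The share of all ribosomal RNA genes was higher in Mutyh KO (1.37%) and DKO (1.48%) than in WT (0.733%) and Ogg1 KO (0.351%). That share includes Rs5-8s1, Rn18s and Rn28s1 themselves, so it is not a separate observation. An effect of Mutyh loss on these RNAs cannot be told apart from a difference between single libraries in ribosomal RNA content. Ndufs5 (0.252-fold and 0.249-fold), Plac9a (0.519-fold and 0.428-fold), Foxo6, a forkhead factor of hippocampal neurons (0.690-fold and 0.546-fold), Crip3 and Crhr1 (0.704-fold and 0.640-fold) were lower. Across the 13186 genes, r between both estimates of Ogg1 loss was -0.19 (-0.24 to -0.15, rho -0.11), with 2 genes higher and 9 lower in both by 1.5-fold and 62 opposite. For Mutyh loss r was -0.01 (-0.06 to 0.06, rho 0.05), with 26 higher, 4 lower and 48 opposite. At 1.5-fold, 207 genes were higher and 87 lower in Ogg1 KO against WT, and 26 and 152 in DKO against Mutyh KO. In Mutyh KO against WT they numbered 304 and 23, and in DKO against Ogg1 KO 109 and 101. How many genes independent lists of these sizes would share was not computed, so few refers only to all genes compared. The third pairing, DKO against WT with Ogg1 KO against Mutyh KO, gave -0.18 (-0.23 to -0.13), a sign that depends on which single knockout is set first.

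Of the 73, 98 and 72 genes at least 2-fold higher in Ogg1 KO, Mutyh KO and DKO against WT, 68 were higher in at least 2 comparisons. Higher at least 2-fold in all 3 were 38 genes, among them Ttr, Kl, Folr1, Aqp1, Clic6, Igf2, Igfbp2, Cd74, H2-Aa and Malat1, and 0 were lower in all 3. Ogg1 KO and Mutyh KO shared 61 higher genes where independent lists would share 0.543 and simulated unchanged libraries 2.40 in either direction, Ogg1 KO and DKO shared 39 (0.399 and 2.30), and Mutyh KO and DKO 44 (0.535 and 3.0). Shared lower genes numbered 4, 3 and 2. The correlations of the log2 ratios were 0.63, 0.57 and 0.71, against 0.48 to 0.50 in simulated unchanged libraries, and the covariances 0.0406, 0.0317 and 0.0402, against 0.0221 when simulated libraries varied by 10%. Part of the excess may come from the 1 WT library that all 3 comparisons share, since the simulated genes varied independently of each other. Genes that differ together in the WT library, as choroid plexus genes did, were not simulated. The excess therefore does not separate genotype from the WT sample.

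**Figure D4:**
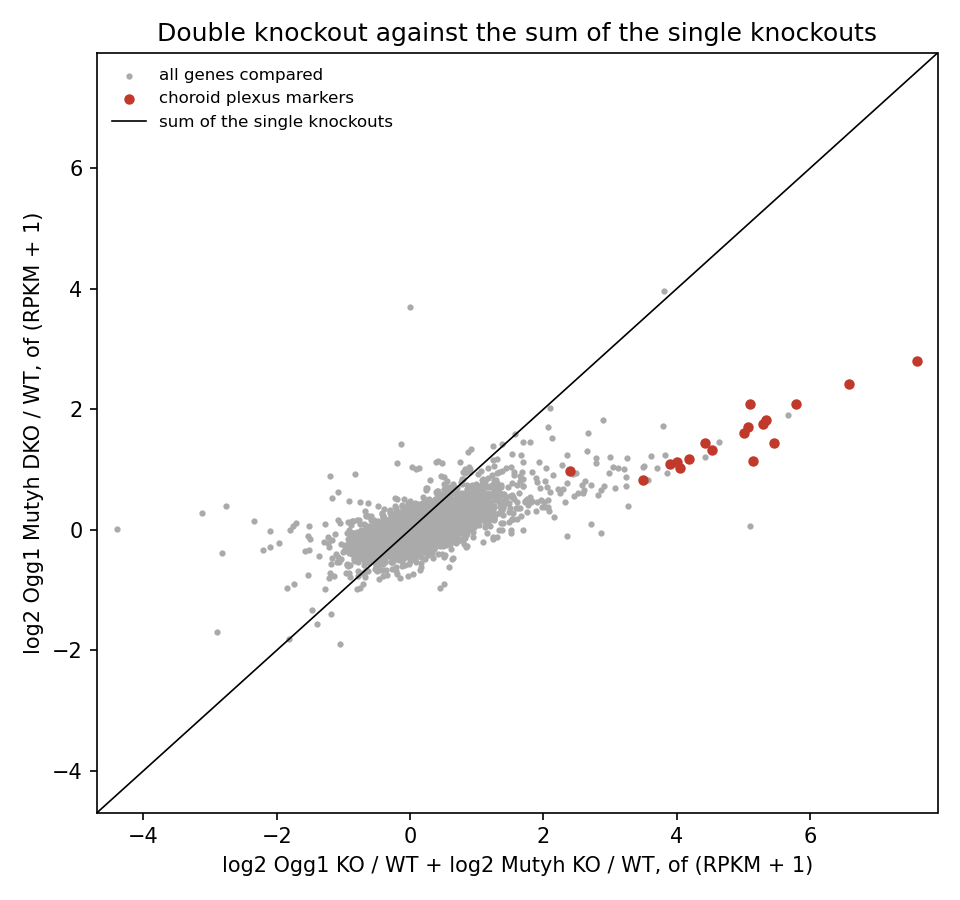
Log2 ratio of DKO to WT against the sum of the log2 ratios of Ogg1 KO and Mutyh KO to WT, 1 point per gene. Of 13186 genes, 190 lie at least 1 log2 unit from the line of equal values, 39 above and 151 below it.

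The combined loss was compared with the sum of the single losses on the log2 scale. The largest departures above that sum were Alb (4.40), Gh (3.70), Rnu1a1 (3.15, from 1 to 7 reads per library), Actc1 (2.48) and Rn7sk (2.10). The largest below it were Xist (-5.03) and the choroid plexus genes Ttr (-4.81), Kcnj13 (-4.16), Kcne2 (-4.02) and Prlr (-4.00). Departures of at least 1 numbered 39 above and 151 below the sum. On the log2 scale a departure equals the DKO and WT values minus both single-knockout values, so a low WT value lowers it as a low DKO value does. A value that stands apart in 1 single knockout also moves it. Alb had 0 reads in Ogg1 KO against 752 in WT and 761 in DKO, and Actc1 had 0 against 128 and 144. Xist had 10307 reads in Mutyh KO against 14 in WT and 29 in DKO. For these genes the DKO library does not itself stand apart from WT as the single knockout does.

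Among genes within 10 Mb of Ogg1, 2.70% (3 of 111, 0.561 to 7.70) differed at least 1.5-fold in Ogg1 KO against WT, 7.21% (8, 3.16 to 13.7) in DKO against WT and 3.60% (4, 0.990 to 8.97) in DKO against Mutyh KO, where 2.23%, 1.97% and 1.33% of other genes did. The share near Ogg1 was the same 2.70% (0.561 to 7.70) in Mutyh KO against WT and in DKO against Ogg1 KO, pairs that do not differ in Ogg1 genotype. Within 10 Mb of Mutyh the shares were 3.01% (5 of 166) in Mutyh KO against WT, 3.01% in DKO against WT and 1.81% (3) in DKO against Ogg1 KO, where 2.47%, 2.0% and 1.59% of other genes did, and 1.20% (2) in Ogg1 KO against WT and in DKO against Mutyh KO. The only neighbour that differed the same way on both backgrounds was Camk1 for Ogg1 and Ndufs5 for Mutyh. The share in DKO against WT near Ogg1 was 6.15% within 5 Mb and 6.22% within 20 Mb, where 1.99% and 1.95% of other genes differed. It was 1.80% with a pseudocount of 5 RPKM, and the share in Mutyh KO near Mutyh was 0.893% among genes of at least 5 RPKM.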

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

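The tests of explanations in this part were chosen only after the result was seen. What drew attention was a loss that went with opposite directions on the 2 backgrounds: a gene at least 2-fold higher against WT and at least 2-fold lower in the DKO against the other single knockout, or the reverse. The difference between backgrounds was not tested in any case, since each genotype had 1 library. Of 15 such genes, 10 are on the choroid plexus list, 13 were opposite for loss of Ogg1 and 4 for loss of Mutyh. All of them had opposite signs for both losses, so this split comes from the 2-fold limit. Kcnj13, for example, had log2 ratios of -1.01 in DKO against Mutyh KO and -0.73 in DKO against Ogg1 KO. Departures from the sum of the single knockouts, in log2, were -4.81 for Ttr, -4.16 for Kcnj13, -4.02 for Kcne2, -4.00 for Prlr, -3.53 for F5, -3.40 for Slc4a5, -3.22 for Wfdc2, -3.04 for Col8a1, -3.01 for Clic6, -2.87 for Kl, -2.73 for Rdh5, -2.68 for Otx2, -2.25 for Beta-s and -2.20 for Ltc4s. Rnu1a1 departed the other way, by 3.15, on 5, 1, 1 and 7 reads. Lists were held to 1.5-fold: the choroid plexus list had opposite medians for both losses, with a median departure of -3.28, the same quantity for either loss, and the blood list for loss of Ogg1, with -1.92.

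Choroid plexus transcripts were lowest in WT, intermediate in DKO and highest in both single knockouts. A lower share of neurons in the knockout samples would raise markers of the other cell types alike; the upper quartile of log2 ratios to WT in Mutyh KO reached 1.68 for blood and 0.12 for astrocytes, below the lower quartile of 2.17 for the choroid plexus, and the same order held in Ogg1 KO (1.03 for blood against 1.90), which argues against it as the whole cause. A different share of choroid plexus tissue predicts that its genes keep 1 ratio between libraries: 14 to 16 of the 18 members lay within 1.5-fold of their median ratio between knockout libraries but only 8 to 10 against WT, where any expression in the hippocampus itself weighs more, and Prlr rose from 1590 reads in Ogg1 KO to 3677 in Mutyh KO, a library that also differs in sex-linked transcripts, while Tmem72 fell from 522 to 235, so this stays open. Of the 18 genes only 1, Prlr, is also in another list, and 11 were at 1 RPKM or more even in WT. An effect of Ogg1 loss that does not depend on Mutyh would keep the list above 0 in DKO against Mutyh KO, where its median was -0.99, but with 1 library per genotype the spread between animals is unknown and genotype and dissection cannot be told apart.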

How the results depend on the processing

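Of 164 alternative values of the main results 130 stayed within 1.5 times the count or within the interval of the planned setting. The other 34 moved and 0 were labelled as reversed. A count or share has no direction, so for these a reversal was not possible. List medians stayed so in 511 of 525 cases and named genes in 1191 of 1328, with 0 labelled as reversed. Yet 18 list medians near 0 changed sign without being given that label. The 0 therefore depends on how the labels were set, and does not show that directions are stable. In the order Ogg1 KO, Mutyh KO and DKO against WT, then DKO against Ogg1 KO and against Mutyh KO, a pseudocount of 0.1 RPKM gave 182, 210, 158, 98 and 101 genes at least 2-fold different, 364 departures and 153 genes shared between comparisons. A pseudocount of 5 RPKM gave 32, 42, 18, 12 and 11 genes, 65 departures and 26 shared genes, and 1.80% of neighbours of Ogg1 differing in DKO against WT. Both follow from construction, since a pseudocount shrinks ratios of weak genes. With no filter the DKO differed from Ogg1 KO in 85 genes. With a mean of at least 5 RPKM, which leaves fewer genes, the counts were 46, 60, 44, 15 and 22, with 77 departures, 46 shared genes, r of -0.24 for Ogg1 loss and 0.893% of neighbours of Mutyh. A limit of 1.5-fold gave 294, 327, 265, 210 and 178. Leaving out listed genes of other tissues and sex-linked genes, chosen after seeing the data, gave 61 genes for Ogg1 KO against WT, 31 for DKO against Ogg1 KO and 20 for DKO against Mutyh KO. Leaving out small and ribosomal RNA genes, also chosen after seeing the data, gave 31 for DKO against Ogg1 KO. Where construction does not show it, the cause was not tested.

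No paired analysis was possible because each genotype had 1 library, and for the same reason leaving out a library was not possible. Summing transcripts was not run, since the tables give 1 entry per gene. Scaling factors differed from 1 by at most 0.04 in log2. At 17.02 M to 18.20 M reads per library, 1 read per kb is 0.0549 to 0.0587 RPKM, so genes near 1 RPKM rest on few reads. WT stands apart for choroid plexus and heat shock genes, and a recount without it can use only comparisons between knockouts.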

Other observations

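The tests of explanations in this part were chosen only after the result was seen, as were the genes named here. Malat1, a nuclear noncoding RNA, had 18756 reads in WT and was 2.07-fold higher in Ogg1 KO, 2.13-fold in Mutyh KO and 2.89-fold in DKO (2.84 to 2.94). The angiotensin-converting enzyme gene Ace was 5.37-fold, 6.42-fold and 3.14-fold higher in the same order, and the cation channel gene Trpv4 5.64-fold, 6.46-fold and 3.0-fold, both following the order of the choroid plexus list. A2m, the protease inhibitor alpha-2-macroglobulin, was 7.67-fold higher in Mutyh KO (6.45 to 9.16) and 2.24-fold and 2.30-fold in Ogg1 KO and DKO. Cox8b, a respiratory chain subunit of muscle and brown fat, had 79 reads in Mutyh KO against 9 in WT (9.28-fold, 4.65 to 21.03).

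The Mutyh KO library held both Xist (10307 reads, 84.8% of its length covered) and Y-linked reads (289 for Ddx3y against 816 in WT). In the other libraries Xist had 14 to 29 reads, so each difference from the Mutyh KO library, including that of DKO, is also one in sex-linked content, and the sex of the animals was not stated. Prl had 48 reads in DKO and 0 in WT, and Pomc 38 against 6 (6.30-fold, 2.64 to 18.3), as Gh was also higher there. Entpd4 was 2.49-fold WT in Mutyh KO but 1.07-fold and 0.991-fold in Ogg1 KO and DKO, and Wdfy1 was 0.724-fold in Ogg1 KO, 1.05-fold in Mutyh KO and 0.559-fold in DKO, both genes from the strain-variable list. Gm14391 had 228 reads in Mutyh KO and 207 in WT but 5.33 RPKM against 12.1, because its deposited length was 2496 bases in the former table and 946 in the latter.

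Liver and heart muscle transcripts were lower in Ogg1 KO than in the other 3 libraries, with 20.6 reads per M reads against 96.5 in WT for the liver list and 16.7 against 48.7 for the heart list. An effect of Ogg1 loss that does not depend on Mutyh would lower them in DKO against Mutyh KO, where the liver list's median was 0.033 beside -1.39 in Ogg1 KO against WT, but with 1 library per genotype the spread between animals is unknown and this stays open, as does an effect that needs Mutyh, which was not tested. A single source of liver and heart reads in the other 3 libraries predicts fixed proportions: over 42 genes with at least 20 pooled reads chi-square over its degrees of freedom was 1.23 (100.6 over 82), but for the summed reads of both lists it was 4.93, with heart over liver at 0.505 in WT, 0.604 in Mutyh KO and 0.558 in DKO, so a single source stays open too. Alb (752, 723 and 761 reads) and Myh6 (251, 278 and 286) were abundant members. The lists have 26 and 18 members, of which 17 and 11 were at 1 RPKM or more in WT, and 0 are in another list; where these reads came from stays open, and no test of the intestinal genes in Ogg1 KO was made.

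Camk1 and Ndufs5 were the only neighbours of the targeted genes that differed the same way on both backgrounds. Ndufs5 has a near-identical copy, BC002163, which had 1 read in WT and in Ogg1 KO but 124 in Mutyh KO and 149 in DKO. Reads of both copies summed were 1.11-fold WT in Mutyh KO (0.885 to 1.40) and 1.21-fold in DKO (0.972 to 1.51), consistent with reads that moved from one copy to the other, as a sequence variant carried with the Mutyh allele might cause. For Camk1, fewer copies of an otherwise unaltered transcript would leave its coverage ordinary if all its reads came from that transcript. Its covered share of 69.8% in Ogg1 KO and 71.9% in DKO lay at percentiles 4.40 and 4.89 among genes of like length and read number. This argues against fewer unaltered copies only if no reads of the overlapping Ogg1 were counted as Camk1, which cannot be told without strand. Whether the Ogg1 deletion reaches Camk1, or the overlap of these genes moves reads between them, stays open.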
